A study of Mus musculus with 136 samples.

How the data were processed

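RNA was measured by sequencing in 136 libraries from mouse bone marrow-derived macrophages, grown for 6 days in M-CSF per the labels, and from such macrophages labelled J2. Chromatin-associated RNA, which is largely RNA still being transcribed, was measured in 113 libraries: the Nfkb1 and Nfkbid knockout series (30 libraries each, 3 replicates of each genotype at 0, 0.5, 1, 2 and 6 h of lipid A), the Nfkbiz and Bcl3 knockout series (20 each, 2 replicates), an ERK inhibitor series (8 libraries at 0, 15, 30 and 60 min) and a TNFa series (5 libraries). RNA of whole cells was measured in wild-type macrophages given lipid A or TNFa (9 libraries, called the mRNA series), in J2 cells (8) and in macrophages overexpressing IkBz (6). These 23 libraries were taken as whole-cell RNA after the design and the scale of the values, although the extraction text of the labels describes chromatin RNA for them too.

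The authors deposited a table in which each gene has 1 value per library in RPKM (reads per kilobase per 1e6 reads), for 15196 genes with 1 transcript each. The deposited table also gives each gene's start and end as whole-number positions in the mm9 build of the mouse genome. The authors name HISAT2, SAMtools and mm9 in their notes and give neither versions nor the rule by which reads were counted. Tests on the values showed that chromatin libraries were scaled over the whole gene span, introns included: between 94.7% and 98.7% of the values worth 30 reads or fewer lay within 0.02 of a whole number of reads. In these libraries genes with 0 reads and genes with 1 read share the value of 1 read, and the table holds no value of 0. In the mRNA series genes without reads carry a floor worth 1 read in 1e6, so that 41.8% to 44.9% of genes have equal values in any pair of its libraries. Of the 15196 genes, 1778 overlap the span of another gene on the same chromosome, and reads over the shared part cannot be assigned to 1 of them here. Nfkb2, Relb, Nfkbiz, Nfkbid, Il6, Il12b and Tnf were not analysed here because they are not among the genes of the table.

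Depth, in units of 1e6 reads (M), was recovered from the step between values. It was 7.86 to 45.3 M in the chromatin libraries (median 28.8), with the lowest values in replicate 1 of the Nfkb1 series (7.86 to 16.2), and 14.9 to 63.0 M in the J2 and overexpression libraries, where 1818 genes with a single exon were used. Depth was not recovered for the mRNA series. A gene of 20 kb at 1 RPKM is then supported by more than 100 reads in every chromatin library. For such genes the spread between replicates, and not the counting of reads, set the precision. For short genes at low values the counting of reads limits it too, as for Mir1907 (chromosome 15, 50720570 to 50720660). The median residual standard deviation was 0.41 (log2) in the Nfkb1 series, 0.19 in the Nfkbiz series, 0.32 in the Bcl3 series and 0.74 in the Nfkbid series. Replicate 1 of the Nfkbid series had far less of the nuclear RNAs Malat1 and Rmrp than replicates 2 and 3, and whether it holds the same RNA fraction is not stated. It was kept, and fits without it are given.

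Values were analysed as log2(RPKM + 0.5). Each knockout series was fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend), with 1 mean per genotype and time, and knockout was set against wild type at each time. Genes were kept that reached an RPKM of 1 in at least as many libraries as a group has replicates. A gene counted as lower or higher at an adjusted p (Benjamini and Hochberg, per time) under 0.05 and a difference of at least 2-fold. Induced genes came from all 50 wild-type libraries of the 4 series, with the series as a term: adjusted p under 0.05, at least 5-fold over 0 h and a mean of at least 3 RPKM at that time. Overlaps between knockouts were set against the number expected from the sizes alone, with a one-sided Fisher exact test. Differences between knockout effects were tested as contrasts in 1 fit of the 4 series with 40 means. In J2 cells the wild type and Nfkb1-/- have 1 library per time, and they were taken to vary like the 2 replicates of the double knockout. Series with 1 library per condition were described without a test: log2 ratios for sets of genes were placed among 10000 random sets of the same size, matched on expression in 10 bins, with seed 7.

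The replicates of the knockout series carry numbers, and the labels do not say that replicate 1 of both genotypes was handled together. The residuals of same-numbered libraries correlated at 0.61 to 0.92 in the Nfkb1 series, 0.45 to 0.73 in the Nfkbiz series, 0.27 to 0.76 in the Bcl3 series and 0.89 to 0.97 in the Nfkbid series. Fits with the replicate number as a term, once for the series and once for each time, were therefore run as alternatives, and their counts are given for the main results and not for every list and gene.

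Gene lists were tested with camera from limma, with a preset correlation between genes of 0.01 and again with an estimated correlation, for lists with 5 or more genes past the filter. The 22 lists were the NF-kB and IkB family, earlier-described IkBz targets, cytokines, chemokines, immediate-early genes, ERK feedback targets, interferon-stimulated genes, NF-kB primary response genes, effector and tissue-response genes, immunoregulatory genes, TLR4 signalling components, proliferation genes, heat-shock genes, sex-linked genes, nuclear-retained RNAs, and markers of macrophages, neutrophils and their precursors, dendritic cells, lymphocytes, mast cells and basophils, erythroid cells, and stromal cells. They were written from general knowledge.

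The named genes followed a rule: the NF-kB and IkB family, the 10 genes lower and the 10 higher with the largest difference at 2 h whose genotypes did not overlap (with fewer than 5, the 5 largest at another time), all induced genes lower in both Nfkb1-/- and Nfkbiz-/-, up to 4 past the threshold in each list, and a fixed set of 14 genes, the genes lower in both, and 5 per direction above 5 RPKM in the series with single libraries. A gene named outside the rule is marked as chosen after its values were seen, except in full listings and in checks of libraries and neighbouring genes. The tests, thresholds, lists and this rule were set before the data were examined.

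Alternatives were pseudocounts of 0.1 and 1, no filter and a filter of 3 RPKM, centring of each library on its median, robust eBayes, a replicate term, each time fitted alone, a spread shared across the 4 series, an induction threshold of 3-fold, and leaving out each replicate in turn. A replicate term per time, and leaving out replicate 1 of the Nfkb1 or Nfkbid series, were added after the data were seen. The procedures were tested on simulated data that carried changes of known size: at 2 h a change of -3 (log2) was recovered in 88% of genes at the size of the Nfkb1 series, 100% for Nfkbiz, 92% for Bcl3 and 32% for Nfkbid, and a change of -1.5 in 40%, 74%, 34% and 4%. The changed genes had a mean above about 4 RPKM, so these shares do not hold for genes of lower expression. The simulated noise was independent between libraries, unlike the correlated residuals of same-numbered libraries. Tables were prepared with Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and SciPy 1.17.1, read in R with the package data.table (version 1.17.8), and drawn with Matplotlib 3.10.9. All 136 libraries were used.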

Results

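The study asked how p50, which Nfkb1 encodes, and the nuclear IkB proteins IkBz (Nfkbiz), Bcl3 and IkBNS (Nfkbid) shape the response of mouse bone marrow-derived macrophages to lipid A, the part of bacterial endotoxin that activates TLR4. RNA attached to chromatin, mostly RNA in the course of transcription, was followed over 0, 0.5, 1, 2 and 6 h in wild-type cells and in cells labelled as knockouts of each of the 4 genes, each beside its own wild type. The values did not show the loss of any of the 4 transcripts in these series: Nfkb1 RNA was not lower past the threshold, Bcl3 RNA was above wild type, and Nfkbiz and Nfkbid were not analysed here. The genotypes below are those of the labels. Values are RPKM as mean ± standard deviation, n is the number of libraries, and differences are on the log2(RPKM + 0.5) scale with the standard error after the ± sign. The added 0.5 makes these differences smaller than the ratio of the means where a group lies under about 1 RPKM. Adjusted p values are from limma. The Nfkbid series had 1 pair of libraries that stood apart: in replicate 1 of both genotypes the nuclear RNA Malat1 was 6.92 to 19.4 RPKM, against 823 to 1640 RPKM in replicates 2 and 3. The nuclear RNA Rmrp was at most 0.673 RPKM there and at least 749 in the others, and the values of a library summed to 52478 to 66008 RPKM against 20385 to 39539. The labels do not say whether replicate 1 holds the same RNA fraction as the rest, and it enters the Nfkbid fit and the means of the induced genes.

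Lipid A induced the genes of neutrophil-attracting chemokines and of Il1b within 0.5 h, and interferon-related and effector genes later. Across the wild-type libraries of the 4 series (n = 10 per time, 5893 genes tested), 189 genes were induced at least 5-fold at 1 or more times: 86 at 0.5 h, 82 at 1 h, 107 at 2 h and 90 at 6 h. Cxcl2 rose from 0.878 ± 0.906 to 263 ± 284 RPKM at 0.5 h (7.42 ± 0.53), followed by Cxcl1 (6.37), Il1b (6.09), Tnfsf9 (5.74) and Dusp1 (5.21). At 1 h Ccl5 (6.29 ± 0.30), Il1b (6.12), Cxcl2 (5.80), Cxcl10 (5.58) and Cxcl1 (5.56) led. At 2 h Ccl5 (7.53), Cxcl10 (6.94), Il27 (6.42), Gbp5 (6.25) and Rsad2 (5.84) rose most. At 6 h Saa3 led, from 0.317 ± 0.740 to 220 ± 356 RPKM (7.64 ± 0.36), ahead of Ccl5 (6.94), Cxcl10 (6.33), Acod1 (5.92) and Il27 (5.84). In the other direction 113 genes fell at least 5-fold at some time. The wide spread of Cxcl2 and Saa3 came from replicate 1 of the Nfkbid series, and without its wild-type libraries 205 genes were induced. Centring each library on its median gave 305 induced genes, and pseudocounts of 0.1 and 1 gave 250 and 139.

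In macrophages labelled Nfkb1-/- a small set of genes stayed below wild-type levels, and the set changed with time. Nfkb1 RNA itself was not among them (-0.25 at the lowest). At 0.5 h 3 genes fell: Egr1 (12.0 ± 1.91 to 1.06 ± 0.0679 RPKM, n = 3 each; -2.99 ± 0.16, adjusted p 1.1e-12), Kdm6b (13.7 ± 2.88 to 4.27 ± 0.614; -1.56 ± 0.25, 0.0036) and Lfng (-1.31, 0.012; chosen after its values were seen). At 1 h Csf2 fell from 2.35 ± 0.84 to 0.0748 ± 0.0534 RPKM (-2.27 ± 0.22, 1.0e-06). At 2 h the largest differences were in C3 (22.8 ± 3.09 to 2.55 ± 1.07; -2.99 ± 0.36, 1.9e-05), Adamts4 (3.41 ± 1.26 to 0.0294 ± 0.0139; -2.84 ± 0.25, 1.1e-07), Gpr132 (-2.67), Il4i1 (-2.47), Rac2 (-2.23), Batf (-2.22), Rnd1 (-2.13), Micall2 (-2.12), Slc25a10 (-1.70) and Mapkbp1 (-1.61). At 6 h Lcn2 fell from 7.76 ± 4.84 to 0.0446 ± 0.0258 RPKM (-3.77 ± 0.23, 3.0e-11), with Edn1 (-1.60, 0.016) and Fos (-1.45, 0.0046). Higher in the knockout were Kcnj2 (1.31) and Smpdl3a (1.05, chosen after its values were seen) at 1 h, and Neurl3 (1.86), 4930594C11Rik (1.54), Shisa3 (1.16) and Htra4 (1.11) at 6 h.

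Of 4523 genes tested in the Nfkb1 series, 41 were lower at some stimulated time and 6 higher, and 12 of the 41 were among the induced genes. The lower genes numbered 3, 27, 17 and 10 at 0.5, 1, 2 and 6 h and the higher 0, 2, 0 and 4. Before stimulation limma called 0 genes in either direction (1 lower and 1 higher at an unadjusted p under 0.05 and at least 2-fold), while the median gene lay at -0.16. All 3 knockout libraries lay on the same side of all 3 wild-type libraries in each called gene, which a test of this kind selects for and which chance gives in 10% of unselected genes. With a term for the replicate number 92 were lower and 30 higher, and with that term at each time 124 and 59. Other fits gave fewer: 4 and 0 with each time fitted alone, 18 and 0 with a spread shared by the 4 series, and 26 and 4 with a filter of 3 RPKM. Without wild-type replicate 3 or knockout replicate 2 the lower genes numbered 21 and 25. The higher genes numbered 2 without knockout replicate 2, 1 without knockout replicate 3, 1, 0 and 1 without wild-type replicates 1, 2 and 3, and 8 without knockout replicate 1, so that this count of 6 changed with most single replicates.

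**Figure D1:**
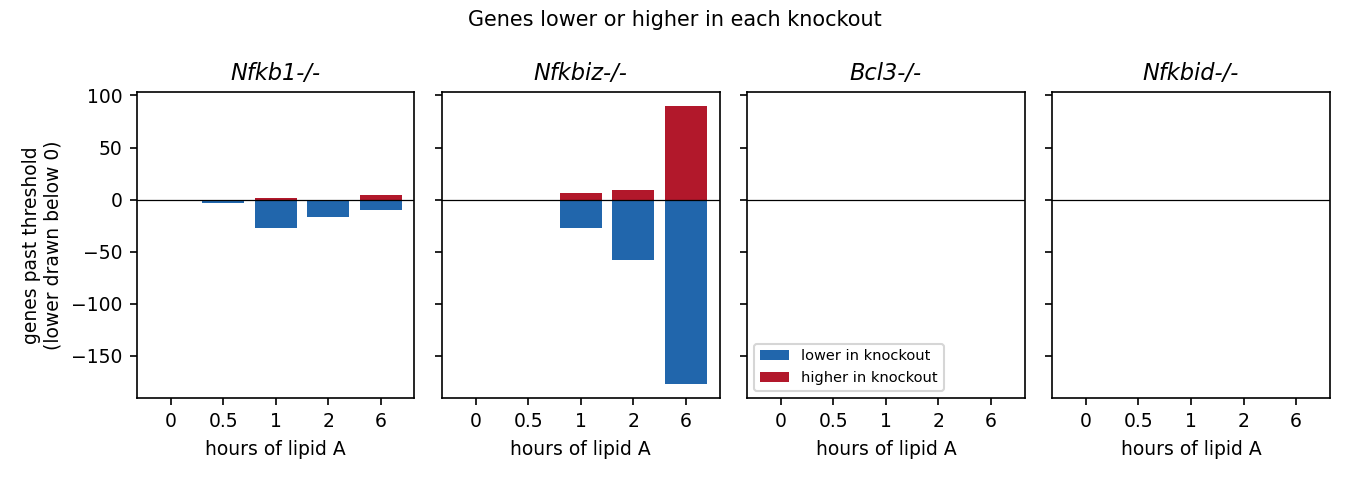
Genes past the threshold (adjusted p under 0.05 and at least a 2-fold difference, limma) in each knockout at each time of lipid A. Genes lower in the knockout are drawn below 0. n = 3 libraries per genotype and time for Nfkb1 and Nfkbid, n = 2 for Nfkbiz and Bcl3.

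As groups, some of the lists were lower than the other genes in Nfkb1-/- cells. At 0.5 h these were the ERK feedback targets (median -0.40 over 7 genes, all 7 below 0; camera adjusted p 6.1e-13, 0.0012 with an estimated correlation) and the immediate-early genes (-0.55 over 14, 11 below 0; 6.1e-13, 0.0023), although Egr1 alone passed the threshold in either list. At 6 h the earlier-described IkBz targets were lower (-1.24 over 6, all 6 below 0; 4.1e-16, 0.00017), and so were effector and tissue-response genes (-0.69; 5.1e-09, 0.041), immunoregulatory genes (-0.67; 8.6e-09, 0.041) and immediate-early genes (-0.44; 2.4e-07, 0.036). At 2 h the NF-kB primary response genes had a median of -0.81 (4.9e-07), a call that ended with the estimated correlation (0.078), as did those at 2 h for cytokines (0.081), chemokines (0.34), the NF-kB and IkB family (0.20), effector genes (0.078), immunoregulatory genes (0.078) and earlier-described IkBz targets (0.059). Adjusted over the list alone, 4 of 13 NF-kB primary response genes were lower at 2 h, and of 10 cytokines 4 were lower and 1 higher. Interferon-stimulated genes were higher at 1 h (0.77; 4.4e-05, 0.23 with the estimated correlation). Past the threshold at some time were 3 of 6 earlier-described IkBz targets, 3 of 10 effector genes, 2 of 14 immediate-early genes, and 1 gene each of the cytokines, the ERK feedback targets and the immunoregulatory genes, all lower. None was called among chemokines, interferon-stimulated genes, macrophage markers, the NF-kB and IkB family and NF-kB primary response genes, but with a replicate term 2, 0, 0, 1 and 1 genes of these lists were lower, and with the term at each time 5, 0, 0, 1 and 5 were lower and 1, 3, 1, 0 and 2 higher. With the 2 terms 4 and 6 of 10 cytokines, 5 and 7 of 14 immediate-early genes and 5 and 6 of 11 immunoregulatory genes were lower. None was called in any of these fits among nuclear-retained RNAs, proliferation genes, TLR4 signalling components, heat-shock genes or sex-linked genes.

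In macrophages labelled Nfkbiz-/- more genes passed the threshold than in Nfkb1-/-, most of them at 6 h. The spread between replicates was smaller in that series (0.19 against 0.41), and with a spread shared by the 4 series 31 genes were lower against 18, so the counts do not measure the reach of the 2 genotypes. At 2 h the largest falls were in Dusp1 (17.4 ± 3.40 to 0.513 ± 0.0753 RPKM, n = 2 each; -4.13 ± 0.29, adjusted p 4.0e-06), Lrrc25 (-3.73), Saa3 (-2.69), Rac2 (-2.67), Tnfrsf1b (-2.40), Adamts4 (-2.38), Batf (-2.26), Fth1 (-2.26), Ccl7 (-2.19) and Serp1 (-2.17). By 6 h Saa3 had fallen from 112 ± 15.8 to 1.55 ± 0.235 RPKM (-5.77 ± 0.25, 8.5e-09), Lcn2 from 13.9 ± 1.66 to 0.0624 ± 0.00596 (-4.68 ± 0.12, 1.5e-11) and Edn1 by 1.91. Il10 was lower at 2 h (-1.78 ± 0.25, 0.0014) and higher at 6 h (1.01 ± 0.25, 0.016). Nfkbia, which encodes IkBa, fell from 72.8 ± 1.71 to 28.5 ± 5.20 RPKM at 2 h (-1.35, 0.0032). Higher in the knockout at 2 h were Tnfsf4 (0.777 ± 0.0967 to 6.39 ± 0.437 RPKM, a difference of 2.43 ± 0.28, adjusted p 0.00027), Mir1907 (1.91), Vcam1 (1.56), Loxl2 (1.41), Pilra (1.36), Cst7 (1.13), Arl5b (1.08), Pik3cb (1.06) and Actn1 (1.03). Mir1907 is very short, so the counting of reads also limits its value.

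Of 4885 genes tested in the Nfkbiz series 208 were lower at some stimulated time, 31 of them induced, and 98 higher, 15 of them induced. The lower genes numbered 0, 27, 58 and 177 at 0.5, 1, 2 and 6 h and the higher 0, 6, 9 and 90. At 0 and 0.5 h limma called 0 genes (22 lower and 6 higher at an unadjusted p under 0.05 and at least 2-fold at 0 h, 10 and 3 at 0.5 h). Both knockout libraries lay beyond both wild-type libraries in each called gene, which the test again selects for and chance gives in 33.3% of unselected genes. At 6 h the median gene lay at -0.24, and relative to the median 91 genes were lower and 165 higher at that time, with all 91 among the 177. Over all stimulated times centring left 125 lower and 175 higher, so that 41.7% of called genes were lower instead of 68.0%. Without wild-type replicate 1 the lower genes numbered 71 and the higher 50, and without knockout replicate 1 they numbered 134 and 60. Without knockout replicate 2 the higher genes numbered 62.

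Among the lists, the largest share of genes lower in Nfkbiz-/- was in its earlier-described targets, of which 5 of 6 were lower: Lcn2, Cebpd (-1.70 at 2 h, -2.40 at 6 h), Edn1, Ccl2 (-2.06 at 2 h) and Ebi3. That list had a median of -1.48 at 2 h (camera adjusted p 1.3e-06, 0.0495 with an estimated correlation) and -1.98 at 6 h (0.00074, 0.36). Immunoregulatory genes had a median of -1.35 at 2 h (1.3e-06, 0.031), with 5 of 11 lower at some time and 1 higher. Effector and tissue-response genes had a median of -1.49 at 6 h (0.0011, 0.50), with 7 of 11 lower, among them Saa3, Lcn2 and Edn1. Lower and higher genes numbered 4 and 2 of 14 chemokines (Ccl3 -2.16 at 2 h and Cxcl9 1.68 at 6 h), 3 and 2 of 10 cytokines, 3 and 0 of 15 immediate-early genes, 0 and 1 of 13 interferon-stimulated genes (Gbp2, 1.20 at 6 h), 0 and 1 of 7 macrophage markers (Mertk, 1.72 at 6 h), 1 and 0 of 5 of the NF-kB and IkB family (Nfkbia), 4 and 0 of 14 NF-kB primary response genes (Sod2, -2.12 at 6 h), and 3 and 0 of 10 proliferation genes (Mki67 -1.22, Top2a -1.13, Cdk1 -1.04 at 6 h). Relative to the median gene these 3 proliferation genes fell short of the threshold (-0.97, -0.89 and -0.79), as did 3 other genes of the lists. Adjusted over the list alone, 6 NF-kB primary response genes and 5 chemokines were lower at 2 h and 1 chemokine higher. With a replicate term the lower genes numbered 9 of the NF-kB primary response genes, 7 of the chemokines, 5 of the cytokines and 2 of the NF-kB and IkB family, and 1 TLR4 signalling component was lower where the fit without the term had none. None was called among ERK feedback targets, nuclear-retained RNAs, heat-shock genes or sex-linked genes.

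Bcl3 and Nfkbid gave no gene past the threshold. In the Bcl3 series (4740 genes, n = 2 each) limma called 0 genes lower and 0 higher, with 20 and 31 at an unadjusted p under 0.05 and at least 2-fold at some stimulated time. The RNA of Bcl3 itself was higher in the libraries labelled Bcl3-/-: 2.43 ± 0.32 against 8.84 ± 0.0736 RPKM at 0 h (1.68 ± 0.33, adjusted p 0.36) and 9.07 ± 0.668 against 35.2 ± 8.04 at 6 h (1.88 ± 0.33, 0.075). With a term for the replicate number both passed (0.044 and 0.0093), as did Ptx3 at 6 h (1.10, 0.0053), and the term at each time gave Bcl3 0.023 and Ptx3 0.00081 at 6 h, added Hcar2 (1.51, 0.043) and ended the call of Bcl3 at 0 h. Ptx3 and Hcar2 were chosen after their values were seen. Without knockout replicate 2 the same fit called 515 genes lower and 39 higher, and without knockout replicate 1 it called 0 and 1. The median gene lay at -0.13 at 0.5 h and -0.16 at 2 h. No list was called with an estimated correlation (smallest adjusted p 0.20), and 0 genes of any list passed the threshold over all genes; adjusted over the NF-kB and IkB family alone, Bcl3 passed at 0 and 6 h.

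**Figure D2:**
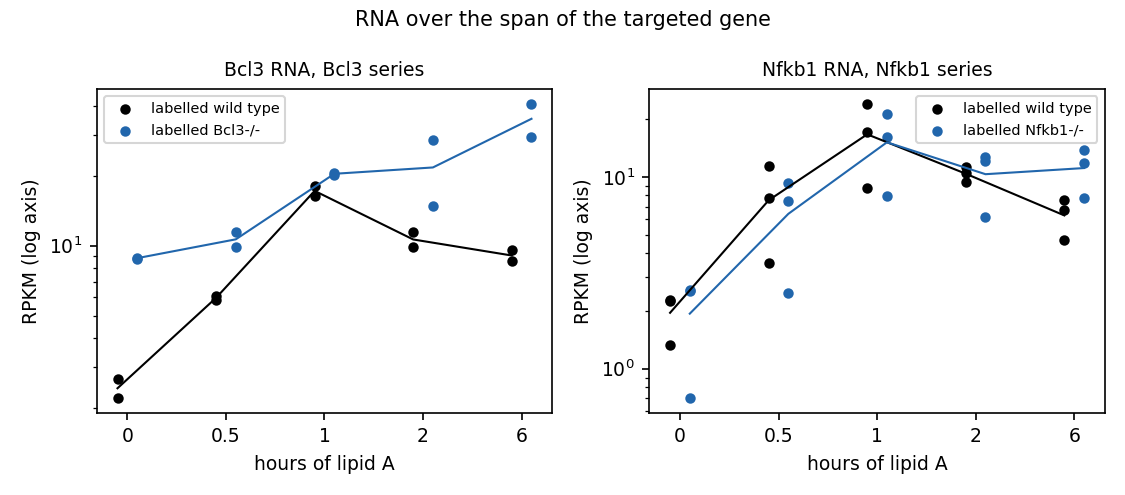
RNA over the span of the targeted gene, 1 point per library, with lines through the means: Bcl3 RNA in the Bcl3 series (n = 2 per genotype and time) and Nfkb1 RNA in the Nfkb1 series (n = 3). A deletion that leaves most of the span in place need not lower these values.

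In the Nfkbid series (5367 genes, n = 3 each) limma called 0 genes in either direction, with 0 lower and 1 higher at an unadjusted p under 0.05 and at least 2-fold. Without replicate 1 of both genotypes it called 0 as well, with 2 to 8 genes lower and 1 to 7 higher per time at an unadjusted p under 0.05 and at least 2-fold. With all replicates and a replicate term, once for the series or at each time, 0 genes were lower and 0 higher at any stimulated time. The term at each time lowered the median residual standard deviation from 0.74 to 0.16. With replicate 1 left out and a replicate term at each time, Spred3 was lower at 6 h (-1.25 ± 0.07, 0.0003; chosen after its values were seen). Spred3 was not called with all replicates. Of the lists, proliferation genes were lower at 0 h (median -0.87 over 10 genes; camera adjusted p 6.1e-19, 0.034 with an estimated correlation). None of the other lists was called with an estimated correlation at any time, neutrophil and granulocyte precursor markers (6 genes) included, and 0 genes of any list passed the threshold. Dendritic cell, lymphocyte, mast cell and basophil, and erythroid markers had no gene past the expression filter in the 4 series, and stromal cell markers had 2 genes in the Nfkbid series alone, both short of the threshold.

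The study's title sets the question whether p50 and IkBz act on the same genes. Among the induced genes 4 were lower in both knockouts: Lcn2, an iron-binding protein of the antibacterial response; Edn1, the peptide hormone endothelin 1; Batf, a transcription factor; and Adamts4, a secreted protease. They lie at chromosome 2, 32240156 to 32243259 (Lcn2), chromosome 13, 42396844 to 42403359 (Edn1), chromosome 12, 87027669 to 87050037 (Batf) and chromosome 1, 173180259 to 173192398 (Adamts4) of mm9. Each was lower at 1 or more stimulated times in each series, not necessarily at every time. Edn1 passed in Nfkb1-/- at 6 h but lay above wild type at 0.5 and 1 h. At 0.5 h its Nfkb1-/- libraries had 0.496, 0.6665 and 0.424 RPKM against 0.121, 0.155 and 0.0537. At 1 h they had 1.76, 3.63 and 1.44 against 1.005, 1.06 and 0.576. Neither rise passed the threshold, and at 2 h the genotypes overlapped. Of 188 induced genes tested in both series 12 were lower in Nfkb1-/- and 31 in Nfkbiz-/-, so that 1.98 shared genes were expected (one-sided Fisher exact p 0.1145). With a replicate term 10 were shared against 6.18 expected (p 0.0542), adding Ccl7, Dusp1, Ebi3, Il10, Il4i1 and Rnd3, and with that term at each time 23 against 10.5 (p 1.97e-06). The 4 numbered 0 without Nfkb1 wild-type replicate 2, 1 without wild-type replicate 3, and 2 without wild-type replicate 1, knockout replicate 1 or Nfkbiz wild-type replicate 1. Bcl3-/- and Nfkbid-/- had no gene past the threshold, so that no other pair could share one.

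In the fit without a replicate term most of the shared genes were not among the induced. Shared genes outside the induced were not counted with a replicate term, so this share holds for that fit alone. Of all 4156 genes tested in both series, 18, the 4 induced genes included, were lower in both against 1.91 expected (one-sided Fisher exact p 3.99e-14). Among the 3968 that were not induced 14 were shared against 1.19 expected (p 1.02e-12), Rac2, Micall2, Slc25a10 and Mapkbp1 among them. The Fisher test takes genes as independent and equally likely to be called. Some shared genes are neighbours: 1110008P14Rik lies within 50 kb of Lcn2, and Fcer1g within 50 kb of Adamts4. These p values, and those for the induced genes above, may therefore be too small. C3 fell in Nfkb1-/- (-2.99 at 2 h). In Nfkbiz-/- it was short of the threshold at 1 h (-1.37 ± 0.35, adjusted p 0.094) and 2 h (-0.25 ± 0.35, 0.79), passed at 1 h with a replicate term at each time (0.0033), and did not pass the test of the difference between the knockouts. Of the 82 genes higher in Nfkbiz-/- that were tested in both, 3 were lower in Nfkb1-/- against 0.81 expected (Gpr132, Lfng and Procr). 4930594C11Rik was the 1 gene higher in both (0.0789 expected), and Kcnj2 was higher in Nfkb1-/- and lower in Nfkbiz-/-. Lfng and Procr were chosen after their values were seen.

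**Figure D3:**
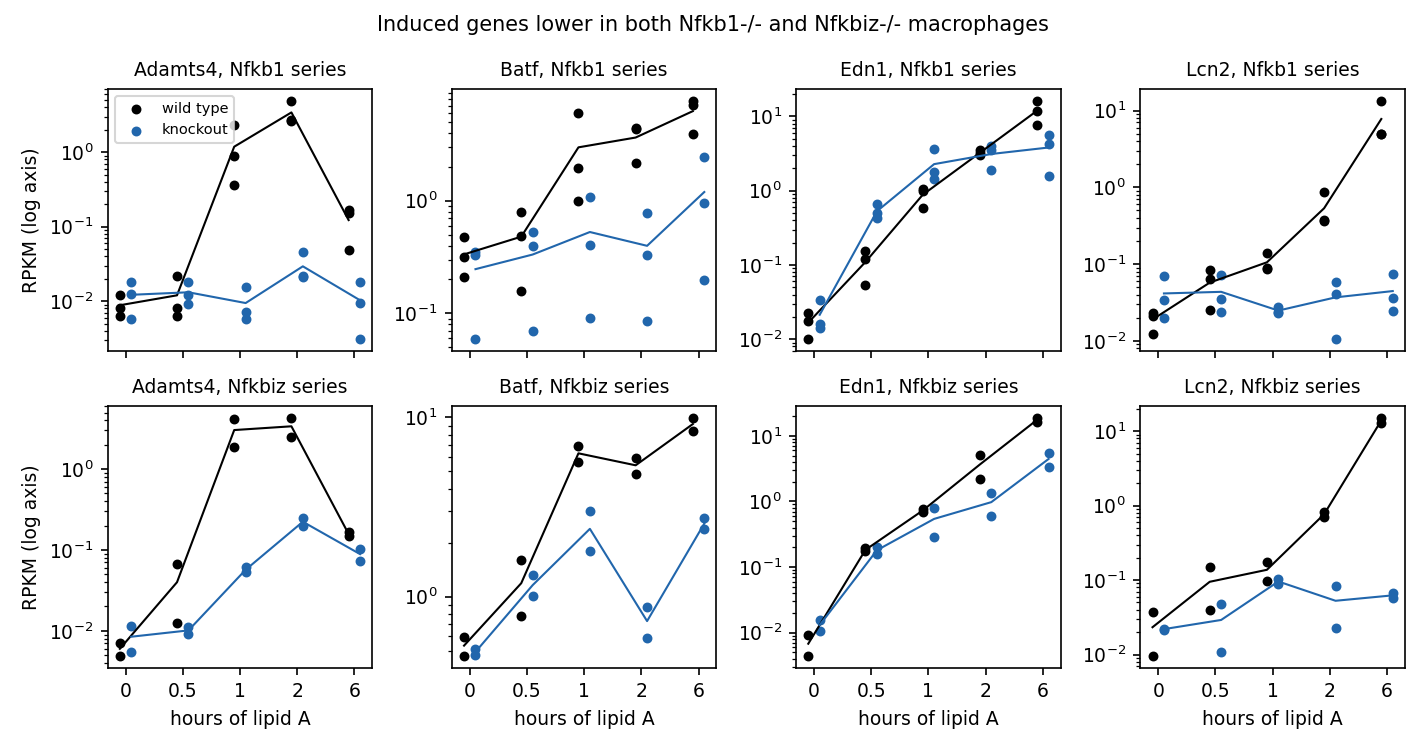
The 4 induced genes lower in both Nfkb1-/- and Nfkbiz-/- macrophages over 6 h of lipid A. Points are single libraries (n = 3 per genotype and time in the Nfkb1 series, n = 2 in the Nfkbiz series), lines join the means, and the axis is logarithmic.

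A test of the difference between the knockout effects asked which genes depended on p50 and IkBz to unequal degrees. Its spread is shared by the 4 series, the wide one of Nfkbid included. On simulated genes with a mean above about 4 RPKM it recovered 56.5% of differences of 4 (log2) at 2 h. A gene that did not pass, C3 included, may therefore still differ between the knockouts. At 2 h 2 genes of 6113 passed: Tnfsf4 (0.04 in Nfkb1-/- against 2.43 in Nfkbiz-/-; difference -2.39 ± 0.50, adjusted p 0.029), and Batf3 (-0.68 against 0.68; -1.36 ± 0.27, 0.024; chosen after its values were seen). Leaving out any of the 10 replicate series left 0 or 1 of these (1 without Nfkb1-/- replicate 3, Nfkb1 wild-type replicate 1 or Nfkb1 wild-type replicate 2), and median centring, a pseudocount of 0.1 or a filter of 3 RPKM left 0, while a replicate term gave 13 and that term at each time 75. At 6 h 8 genes differed (100 and 275 with the 2 terms), led in size by Xylt2 (1.01 against -3.08; 4.09 ± 0.55, 7.3e-07; chosen after its values were seen) and Tnfsf4 (-3.48). Against Nfkbid, 4 genes differed at 2 h (24 and 61 with the 2 terms): Adamts4 (-2.86 ± 0.55, 0.0066), Batf (-2.57), Mapkbp1 (-1.80) and 6530402F18Rik (-1.76). Against Bcl3, 0 genes differed at 2 h (limma, 15 at an unadjusted p under 0.05 and at least 2-fold; 9 and 34 with the 2 terms) and Csf2 alone at 1 h (-2.73 ± 0.50, 0.0058; 12 and 60 genes with the 2 terms).

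The J2 cells were used to ask whether p52, the product of Nfkb2, covers for p50. Among 6436 genes limma called 0 lower and 0 higher in Nfkb1-/- Nfkb2-/- cells than in wild type at 2 h, with 141 and 69 at an unadjusted p under 0.05 and at least 2-fold and a smallest adjusted p of 0.086, in a fit with 2 residual degrees of freedom. Without the expression filter 53 genes were lower, and with a pseudocount of 1 4 genes. The wild type and Nfkb1-/- had 1 library per time and the double knockout 2. Differences between the cultures of each genotype therefore cannot be told apart from the genotype in the values that follow. Of the 4 induced genes lower in both Nfkb1-/- and Nfkbiz-/- Edn1 alone is given here, and C3 is not among them. At 2 h C3 was 59.2 RPKM in wild type, 6.54 in Nfkb1-/- and 11.5 and 7.25 in the double knockout, and Edn1 was 5.47, 7.10, and 2.83 and 2.36. Nfkb1 RNA was 145 RPKM in wild type, 40.4 in Nfkb1-/- and 37.4 and 32.1 in the double knockout. The double knockout against Nfkb1-/- gave 0 genes in that fit (limma, 156 lower and 52 higher at an unadjusted p under 0.05 and at least 2-fold), which with 1 Nfkb1-/- library per time leaves the question of p52 open.

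TNFa activates NF-kB by another receptor, and the study used it to ask which genes are selective for lipid A. In RNA of whole cells (1 library per time, no test) the 4 genes lower in both knockouts rose with lipid A and hardly with TNFa: the median of the largest log2 fold over 0 h was 4.87 against 0.15. Edn1 reached 6.79 with lipid A and 0.03 with TNFa, Lcn2 5.13 and 0.26, Batf 4.61 and 0.71, and Adamts4 3.84 and 0. The difference between the stimuli, 4.39, lay at percentile 99.6 of random sets of 4 induced genes, beside 1.21 for the 185 other induced genes. The 23 genes shared when the replicate term was used at each time had a difference of 2.32 (percentile 99.985), although they did rise with TNFa (median 2.71). The 185 genes had a median of 2.49 with TNFa, but they are the induced genes outside the 4 and hold most of the 23. Nfkbia responded nearly alike (5.26 and 4.70) and Cxcl1 strongly to both (9.88 and 7.14). In chromatin RNA the 4 genes had a median of 0.09 with TNFa, beside 1.77 for the 185 other induced genes. The 23 had a median of 0.91 (percentile 2.7 of random sets of induced genes). Where a gene had no reads the mRNA table holds a floor, so the folds of Edn1 and Adamts4 depend on that floor.

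The overexpression libraries asked whether added IkBz lets TNFa switch on the genes that need it (1 library per condition, no test). Of the 4 shared genes Lcn2 was the 1 that was higher by more than 1 with added IkBz: by 3.99 at 0 h, 2.87 with TNFa for 2 h and 1.42 with lipid A for 2 h. The median of the 4 was 0.11, -0.05 and -0.33. Without stimulation Saa3 (6.15), Slc13a3 (6.06), Marco (4.20) and Fpr1 (4.09) were also higher, while the mannose receptor gene Mrc1 was lower in the 3 conditions (-3.88, -4.11, -3.43). The macrophage markers as a list were not lower (medians 0.19, 0.31 and 0.000847 over 7 genes). Effector and tissue-response genes had a median of 1.12 at 0 h, -0.06 with TNFa and -0.26 with lipid A, and earlier-described IkBz targets 0.20, 0.09 and -0.21. Chemokines had medians of 0.14, -0.55 and -0.47, cytokines 0.22, -0.01 and -0.66, and interferon-stimulated genes 0.36, -0.17 and -0.56, so that these 3 lists lay above 0 without stimulation and below it with lipid A. The largest shift of any list was in neutrophil and granulocyte precursor markers, with medians of 3.12, 3.25 and 2.51 over 9 genes, above all 10000 random sets. With TNFa Mpo (5.47), Prtn3 (4.92), Elane (4.34) and Ctsg (3.80) led. Whether Lcn2 was higher through added IkBz or through a change in the cells that also raised these markers was not tested. Proliferation genes were lower (-0.65, -0.50, -0.48). At least 5-fold higher were 27, 20 and 15 genes, and lower 2, 7 and 5, of 6510.

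The last comparison asked whether the early genes that need Nfkb1 are those that need ERK signalling, since the design gives p105, the precursor of p50, a part in stabilising an activator upstream of ERK. With the ERK inhibitor (1 library per condition, no test) Egr1 was lower than with DMSO by -4.40 at 15 min, -4.78 at 30 min and -1.11 at 60 min. Before lipid A it differed by -0.22. Fos was lower at 15 and 30 min (-1.93, -1.59), but already by -1.35 at 0 min. Lower too were Dusp5 at 30 and 60 min (-1.74, -2.58) and Kdm6b at 30 and 60 min (-0.81, -1.84). ERK feedback targets had medians of -0.30, -0.64, -1.20 and -1.25 at 0, 15, 30 and 60 min, and immediate-early genes -0.17, -0.78, -0.71 and -0.35, so that both lists were low before lipid A as well (percentiles 0.13 and 0.38 of random sets). The 2 induced genes lower in Nfkb1-/- at 0.5 h, Egr1 and Kdm6b, had a median of -2.79 at 30 min, at percentile 0.745 of random pairs. That is the mean of 2 unequal values (-4.78 and -0.81), and the 4 genes lower at 0.5 h with the replicate term at each time had -0.93. Across the 85 genes induced at 0.5 h the inhibitor effect at 30 min and the Nfkb1-/- effect at 0.5 h correlated (Pearson 0.66, Spearman 0.54; across genes, which are not independent replicates), against 0.08 before stimulation. All 3249 tested genes gave a Pearson correlation of 0.39 and a Spearman correlation of 0.37 at 30 min, so the relation was not confined to the induced genes. In the other direction interferon-stimulated genes were higher with the inhibitor at 60 min (median 1.14), led by Rsad2 (2.03) and Cmpk2 (2.02).

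**Figure D4:**
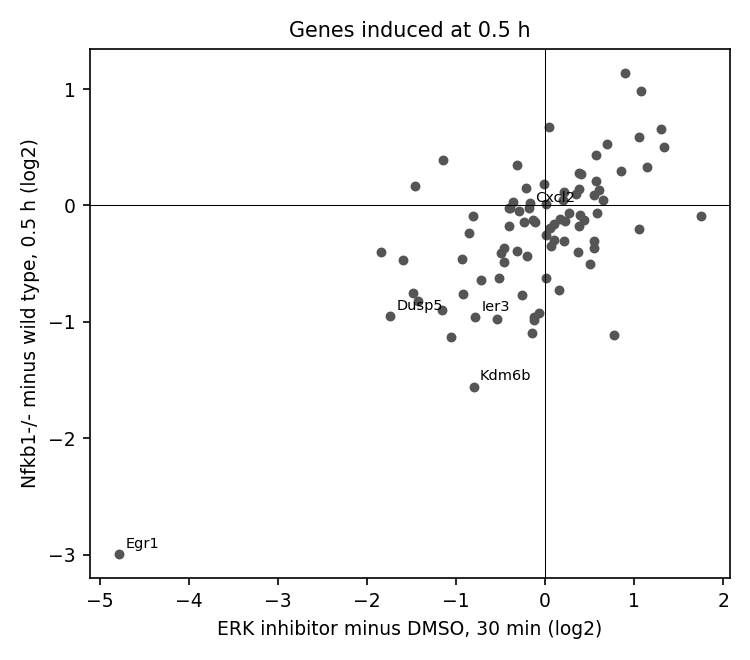
The 85 genes induced by lipid A at 0.5 h. Horizontal, log2 difference between ERK inhibitor and DMSO at 30 min (1 library each); vertical, log2 difference between Nfkb1-/- and wild type at 0.5 h (n = 3 each). Each point is a gene.

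The NF-kB and IkB family genes in the table were read for the knockouts themselves. Nfkb1 RNA in Nfkb1-/- macrophages differed from wild type by -0.11, -0.25, -0.13, -0.07 and 0.76 at 0, 0.5, 1, 2 and 6 h, none past the threshold, while it was lower in the J2 Nfkb1-/- library. Bcl3 RNA in Bcl3-/- was higher at 0 and 6 h, as given. Nfkbiz and Nfkbid were not analysed here, so the loss of these transcripts was not seen. Without a replicate term Nfkbia was the 1 family gene past the threshold in any of the 4 series.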

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

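Of the tests in this part, the search for exchanged labels in the Bcl3 series and the search for neighbouring induced genes were chosen only after the result was seen. The other tests were set beforehand.

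Some knockout effects differed between knockouts in a test of the difference itself. Between Nfkb1-/- and Nfkbiz-/- 2 genes differed at 2 h, Tnfsf4 (-2.39) and Batf3 (-1.36), and 8 at 6 h: Xylt2 (4.09), Tnfsf4 (-3.48), Ptges (2.95), Cpd (2.72), Fcrl6 (-1.55), Clic5 (-1.52), Ovol1 (1.46) and Sectm1a (-1.44). Values are the log2 effect in Nfkb1-/- minus that in the other knockout. Between Nfkb1-/- and Bcl3-/- 1 gene differed, Csf2 at 1 h (-2.73). Between Nfkb1-/- and Nfkbid-/- 3 genes differed at 1 h, Micall2 (-2.45), Fam107b (-2.25) and Csf2 (-2.10), 4 at 2 h, Adamts4 (-2.86), Batf (-2.57), Mapkbp1 (-1.80) and 6530402F18Rik (-1.76), and 1 at 6 h, 6530402F18Rik (-1.49). These counts come from the fit without a replicate term. With the term they were larger: 13 and 100 for Nfkbiz-/- at 2 and 6 h, 12 for Bcl3-/- at 1 h, and 25, 24 and 16 for Nfkbid-/- at 1, 2 and 6 h. The 2 calls at 2 h against Nfkbiz-/- were fragile in other settings: 0 genes remained with median centring, a pseudocount of 0.1 or a filter of 3 RPKM, and 0 or 1 without any single replicate.

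Each strongly induced gene at 1 time gave a group of 10 wild-type libraries. Of 48 such groups 24 held a library far from the other 9, while chance gives such a library in about 1 in 20 independent groups. These groups were not independent. They reuse the same libraries at each time, and the genes were chosen by a fold to which these libraries contribute. The share is therefore a description and not a test. In 23 of the 24 groups the far library was replicate 1 of the Nfkbid series. Its values in RPKM were: Cxcl2 1063 (0.5 h) and 237.8 (2 h); Cxcl1 444.4 (0.5 h), 364.2 (1 h) and 103.1 (2 h); Il1b 338 (1 h) and 258 (2 h). Tnfsf9 had 677.5 (0.5 h), 648.5 (1 h), 121.4 (2 h) and 50.99 (6 h), Dusp1 452 (0.5 h) and 168 (1 h), and Ccl5 715.2 (6 h). Cxcl10 had 322.3 (0.5 h), 1416 (1 h), 4355 (2 h) and 3107 (6 h), Saa3 2.225 (0.5 h) and 1232 (6 h), and Acod1 362.6 (1 h), 696.7 (2 h) and 891.7 (6 h). The remaining value was Rsad2 at 0.5 h in replicate 1 of the Nfkb1 series, 1.302 RPKM against 13.4 to 34.8 in the other 9. The knockout library of replicate 1 in the Nfkbid series carried the same low Malat1 as its wild type, so the difference belongs to the replicate and not to the genotype. Its cause was not tested.

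The splits of the 6 replicate series into groups of 3 give 10 splits, too few for a share under 0.05. For Nfkb1 the real split gave 47 genes in either direction and 1 of 10 splits gave as many. The highest other split gave 38, and it put both replicate 1 series, the shallowest libraries, on the same side. The other splits that did so gave 5, 7 and 0. Each of the splits that part all same-numbered replicates, as the real one does, gave 0. With the replicate term, which compares within the numbers, the real split gave 92 lower and 30 higher. For Nfkbid the real split gave 0 genes, so that 10 of 10 splits gave as many, which any data would give against a count of 0. The highest other split gave 1532. The splits with replicate 1 of both genotypes together gave 2, 651, 6 and 1532, and a split that parted them gave 88. Replicate 1 alone therefore does not set these counts. Splits parting all same-numbered replicates gave 0. For the effects that differ between Nfkb1-/- and Nfkbid-/- at 2 h the real value was 4, 1 of 10 splits of the pairs gave as many, and the highest other split gave 0. For induction by lipid A chance can be excluded: of 100 splits, each a new assignment of the times within each replicate series, 1, the real one, gave 189 induced genes, and the highest other gave 30.

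The Bcl3 RNA of the libraries labelled Bcl3-/- was above that of their wild types at each time, which is the reverse of what the loss of a transcript gives. An exchange of the labels between the genotypes would put the libraries labelled wild type outside the range of the other series' wild types. That held for 3 of 10, by small margins at 0 and 1 h, while 10 of 10 libraries labelled Bcl3-/- lay above that range, so the tables argue against an exchange. A change over the whole region would reach the neighbours, and the 3 nearest tested genes on each side had a median of -0.21 at 6 h, against 1.88 for Bcl3. The farthest, Smg9, starts at 25185000 on chromosome 7, far from Bcl3 (20393810 to 20408104), and says little of a local change. The others lay from -0.36 (Gemin7) to -0.10 (Pvr), with a standard error of 0.67 for Ceacam16. What stays open is whether the altered allele makes a transcript that is more abundant or more stable, or whether the cell no longer holds its own Bcl3 transcription down. The labels do not give the allele, and no biological explanation was tested.

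The 14 genes lower in both Nfkb1-/- and Nfkbiz-/- without counting as induced might reflect a difference between the mouse lines that was there before stimulation. Their median difference at 0 h was -0.15 in the Nfkb1 series, where the median of all genes was -0.16, and -0.11 in the Nfkbiz series, while the medians of their lowest stimulated values were -1.54 and -1.57. The tables therefore argue against a difference present at 0 h. Transcription running on from an induced neighbour would place them beside such genes. Of the 14, 2 lay within 50 kb of an induced gene (1110008P14Rik beside Lcn2 and Fcer1g beside Adamts4), beside 3.19% of 3954 other genes, so this does not account for the other 12, although genes missing from the table could not be counted. In wild type the median of their largest rise over 0 h was 0.87, against -0.07 for the other genes, and 10 of the 14 rose past the adjusted p short of 5-fold. A candidate explanation is that they belong to the same p50 and IkBz dependent response and rise less, which is a hypothesis found and looked at in the same data.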

How the results depend on the processing

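The replicate term per time, leaving out replicate 1 of both genotypes together, and the 23 shared genes taken from the fits with a replicate term per time were chosen after seeing the data. All other alternatives were planned. Of the counts and values that answer a comparison 1 changed sign, near 0 and without a test: the median of the 4 shared genes with added IkBz and TNFa, -0.05, was 0.06 with a pseudocount of 0.1 and 0.0017 with median centring.

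The replicate term moved 5 results. It gave 92 genes lower and 30 higher in Nfkb1-/-, 2 higher in Bcl3-/-, 10 induced genes lower in both Nfkb1-/- and Nfkbiz-/-, and 13 whose effects differ between these knockouts at 2 h. The term per time gave 124, 59, 3, 23 and 75. The 41 and 6 genes of the fit without it all stayed past the threshold with the term. By construction the term takes out what same-numbered libraries share, and the residual standard deviation fell from 0.41 to 0.17 in the Nfkb1 series and from 0.74 to 0.16 in the Nfkbid series with the term per time. Since the labels do not state that the replicates were paired, both fits are given. With replicate 1 left out of both genotypes and the term per time, 120 genes were lower and 74 higher in Nfkb1-/-, and 1 lower in Nfkbid-/-. With each time fitted alone, 4 genes were lower and 0 higher in Nfkb1-/-, 124 lower in Nfkbiz-/-, and 0 induced genes lower in both. With the spread shared across the 4 series, 18 were lower and 0 higher in Nfkb1-/-, 31 lower and 12 higher in Nfkbiz-/-, and 2 induced genes lower in both. That sharing lends the wide spread of the Nfkbid series to the others by construction.

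Median centring gave 125 genes lower and 175 higher in Nfkbiz-/-, 1 higher in Bcl3-/-, 305 induced, 0 effects that differ at 2 h, and a lipid A to TNFa difference of 4.93. A pseudocount of 0.1 gave 460 genes lower in Nfkbiz-/-, 0 effects that differ, 4.88 for lipid A against TNFa and a median of -1.78 for the ERK feedback targets with the ERK inhibitor at 30 min. A pseudocount of 1 gave 3 genes higher in Nfkb1-/-, 130 lower and 64 higher in Nfkbiz-/-, 1 effect that differs, and 4 lower in the J2 double knockout. Without a filter 2 genes were higher in Bcl3-/- and 53 lower in the J2 double knockout. A filter of 3 RPKM gave 26 lower in Nfkb1-/-, 1 higher in Bcl3-/- and 0 effects that differ. An induction threshold of 3-fold gave 380 induced genes. With the 23 shared genes the lipid A to TNFa difference was 2.32. Except where construction shows it, the cause of these shifts was not tested.

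Leaving out each replicate in turn gave 21 to 39 genes lower and 0 to 8 higher in Nfkb1-/-, 71 to 248 lower and 50 to 101 higher in Nfkbiz-/-, 0 to 515 lower and 0 to 39 higher in Bcl3-/-, 0 to 0 in both directions in Nfkbid-/-, 0 to 4 induced genes lower in both, 0 to 1 effects that differ, and 182 to 205 induced genes. The value of 515 came without Bcl3-/- replicate 2 and that of 71 without wild-type replicate 1 of the Nfkbiz series. Where this left 1 library in a group, it was taken to vary like the other groups. The other 129 values of these results under the alternatives stayed close to the main ones. Counts stayed within 1.5 times the count. Medians in the series with single libraries moved by less than 0.4849 (log2), the median residual standard deviation between wild-type libraries of a series and time. Of the 29 genes named at 2 h, 27 stayed past the threshold with a pseudocount of 0.1 and 28 with median centring, and all 29 with a pseudocount of 1, robust eBayes and both replicate terms. Leaving the shallowest libraries, replicate 1 of the Nfkb1 series, out of both genotypes gave 48 genes lower and 9 higher without a replicate term.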

Other observations

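Of the tests in this part, the comparison of the ERK inhibitor with each knockout was chosen only after the result was seen.

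Of the 3 genes lower in Nfkb1-/- at 0.5 h Egr1 is an immediate-early and ERK feedback gene, and Kdm6b and Lfng are in neither list. Genes outside the lists such as Ifrd1 (-1.13, chosen after its values were seen) were also lower without passing the threshold. A weaker response of all early genes would lower the rest as well. The 72 genes induced at 0.5 h outside these 2 lists had a median of -0.12 (standard deviation 0.50, quartiles -0.40 and 0.12), against -0.62 for the 13 within them, which leaves a weaker response of the rest open. Lower activity of the ERK pathway would make the ERK inhibitor resemble Nfkb1-/- more than the other knockouts. The correlation across genes induced at 0.5 h was 0.66 for Nfkb1-/-, and the highest of the others was 0.27 for Nfkbid-/- (0.15 for Nfkbiz-/-, 0.09 for Bcl3-/-). Without Egr1 it was 0.52 against 0.33. Across all 3249 tested genes it was 0.39 for Nfkb1-/-, so part of it is not particular to the early genes, and Fos was already lower with the inhibitor before lipid A (-1.35). At 0.5 h Nfkbiz-/-, Bcl3-/- and Nfkbid-/- had 0 genes past the threshold. With so little effect to correlate, their lower values were likely whatever the cause, so the comparison cannot single out ERK. Whether lower ERK activity in Nfkb1-/- cells lies behind part of these differences stays open. It is the hypothesis of the study's design and was looked at here with 1 inhibitor library per time. The inhibitor itself is not named in the labels. In the test of the difference between knockouts at 0.5 h limma called 0 genes (5, 8 and 4 against Nfkbiz-/-, Bcl3-/- and Nfkbid-/- at an unadjusted p under 0.05 and at least 2-fold). With a replicate term it called 0, 0 and 1, and with that term at each time 9, 21 and 14.

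Dusp1, an early gene, was among the genes lowest in Nfkbiz-/- against wild type at 2 h (-4.13) and 6 h (-3.14), and in Nfkb1-/- it was at -0.45 at 2 h and -1.72 at 6 h, the latter past the threshold with either replicate term (adjusted p 0.012 and 0.00016) and not without. Tnfsf4 went the other way: in wild type of the Nfkbiz series it was at 0.113 RPKM at 6 h, in the knockout at 7.37. Il10 was lower in Nfkbiz-/- at 2 h and higher at 6 h, so a single time would have given either direction.

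The overexpression libraries carried high values of neutrophil and granulocyte precursor genes such as Mpo and Prtn3 (5.47 and 4.92 with TNFa) beside low Mrc1 (-4.11), while the 7 macrophage markers had a median of 0.31 with TNFa. Whether added IkBz turned these genes on or whether the cells held more precursors was not tested, and each condition had 1 library. The same holds for the higher Lcn2 in these libraries.

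Nfkb1 RNA did not differ past the threshold in the Nfkb1-/- macrophages at any time (-0.25 at the lowest), whereas it was 40.4 RPKM in the J2 Nfkb1-/- library at 2 h against 145 in wild type. Reads over the whole span of a gene, introns included, would miss a small deletion. Which allele each line carries was not analysed here.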
